A study of Homo sapiens with 25 samples.

How the data were processed

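Bulk poly(A) RNA sequencing was carried out on 25 libraries of hiF-T cells, a human line derived from BJ skin fibroblasts. TERT, which encodes the catalytic subunit of telomerase, was expressed in every library. In the sort set, 20 libraries came from cells that were left ungated or were taken from 4 gates of dye accumulation (low, midlow, midhigh and high), with 4 biological replicates in each of the 5 groups. The drug set held 5 libraries, namely DMSO, DOT1L inhibition and LSD1 inhibition as replicate 1, and no drug and LSD1 inhibition as replicate 2. The labels name the inhibited enzymes but no compound, dose or time, and they do not say which dye level goes with slow division. The library kit given in the labels (NEBNext Ultra II RNA) does not record the strand. Per the submitters' processing notes, reads were aligned with STAR and assigned to genes with HTSeq on hg38 (GRCh38). The sources used here give no version, annotation release or strand setting for these steps.

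The deposited values were raw counts, 1 per Ensembl gene and library, without normalisation by the authors, and each file closed with the HTSeq totals of reads that were not counted. A series-wide table in long form was not used. The files held 58302 genes, of which 57532 had a symbol in the reference gene table and 58039 were found in GENCODE release 29, which gave biotypes and GRCh38 coordinates. That release may not be the one used for counting. Gene counts summed to 15015039 (midlow dye replicate 3) to 20030093 (midlow dye replicate 2) per library. Reads that HTSeq assigned to no feature made up 4.33% to 7.72% and ambiguous reads 7.14% to 7.63% of the reads. Mitochondrial genes took 2.19% to 3.12% of the gene counts. A gene without a count could still lie at up to 3 counts, or 0.150 to 0.200 counts per 1e+06 gene counts (CPM), a limit that covers counting error only. No 2 libraries of 1 group were copies of each other, since the smallest chi-square per degree of freedom between libraries of 1 group was 8.22.

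Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (glmQLFit and glmQLFTest) with TMM factors and filterByExpr (minimum count 10, minimum total 15), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All 20 sort libraries shared 1 fit for high against low dye, midhigh against midlow dye, and high or low dye against ungated cells (14592 genes). A trend was fitted over the 16 gated libraries, with the gates in the order low, midlow, midhigh, high and in equal steps, an assumption because no dye values are given (14419 genes). The LSD1 inhibition libraries were compared with a control group made of the DMSO and the no drug library (14002 genes). The replicate number was not a term of these fits, because the labels state no pairing, and it entered as a block in an alternative. Errors of log2 fold changes are standard errors computed as the absolute log2 fold change divided by the square root of F. CPM values are scaled with TMM and given as mean and SD over libraries. DOT1L inhibition had 1 library and was set against DMSO as a log2 ratio of CPM with a prior count of 2 and without a test.

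Whether the replicate numbers pair the sort libraries was checked by correlating, across genes, the residuals that remained after the group means were removed. All 40 pairs of libraries with the same number correlated above 0.1 (lowest 0.146, highest 0.618, mean 0.455). Of 120 pairs with different numbers 16 did so (highest 0.288). The mean of those 120 (-0.152) is tied to the same-number mean by the removal of group means. The numbers thus pair the samples in general. Pairing was weaker for ungated replicate 3, at 0.146 to 0.354 with its own gates and 0.152 with midlow dye replicate 4. Values from the fit with the replicate block are therefore given beside the results of the sort set. The drug set had only 2 pairs. Removal of the group means makes their correlations equal (0.557) and those across numbers the negative of this (-0.557). They amount to a single free value, which had the sign that pairing gives but is a weak check.

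In all, 28 gene lists were used. These were S phase (DNA replication), G2 and mitosis, cyclin-dependent kinase inhibitors, p53 targets, NRF2 and iron stress, integrated stress response, lysosome, secreted and inflammatory factors, collagen and matrix, contractile, TGF-beta and YAP targets, mesenchymal transcription factors, HOX, pluripotency, epithelial, neuronal, myeloid and erythroid, endothelial, melanocyte and Schwann cell, interferon, cholesterol synthesis, glycolysis and hypoxia, ribosomal protein, mitochondrially encoded, nuclear oxidative phosphorylation, MYC and ribosome biogenesis, immediate early, and replication-dependent histone. The symbols DDX58 (listed also as RIGI) and H3C2 matched no gene. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation, fry, and counts of members adjusted over the list alone were run beside it. The mean log2 CPM of the S phase and of the G2 and mitosis list was compared between the high and low dye libraries by a two-sided exact permutation test. For DOT1L inhibition, the median of each list was ranked among the medians of 10000 random lists matched on expression.

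For high against low dye and for LSD1 inhibition, the genes to name were the 12 with the largest and the 12 with the smallest fold change among called protein-coding genes with a mean of at least 10 CPM and the same direction in every same-numbered pair. The other tested comparisons took 5 each way under the same rule, or the 5 largest values each way where no gene passed. DOT1L inhibition took the 10 largest and 10 smallest ratios among genes at 10 CPM or more in either library. Up to 4 members of each list by smallest p, and 16 fixed genes, could be named in addition. The comparisons, tests, lists and this rule were chosen before the data were examined. Genes of the Y chromosome and XIST were left out.

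The procedure was tested on simulated data with the same group sizes and 200 changed genes. For high against low dye it recovered 53% of 1.5-fold and 75% of 2-fold changes, with 5 false calls among 133. For LSD1 inhibition it recovered 21% and 73%, with 15 false calls among 109. In a further simulated set for high against low dye, the DESeq2 Wald test recovered 87% of 2-fold changes and made 25 false calls. Of 25 unchanged lists, 0 were called. The simulated genes were drawn independently of each other and without a replicate effect, unlike the real libraries. These rates may therefore not hold for the data. The list result does not cover correlation between members. The alternatives were DESeq2 size factors within edgeR, library size alone, no filter, a filter at 5 CPM, the DESeq2 1.42.0 Wald test, the replicate block, a fit of only the groups compared, a linear contrast over 4 gate groups, a prior count of 0.5, a minimum log2 fold change of 1, and each library left out in turn. Fits without ungated replicate 3, fits without high and midhigh dye replicate 3, sign flips within replicate numbers and left-out libraries for the list levels were chosen after seeing the data.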

Results

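RNA was sequenced from hiF-T cells, fibroblast-like cells that express TERT, after a sort on dye accumulation or after drug exposure. The series design describes the sort as one by proliferation status. There were 4 libraries each of ungated, low dye, midlow dye, midhigh dye and high dye cells. The drug set held 1 DMSO, 1 no drug, 1 DOT1L inhibition and 2 LSD1 inhibition libraries. LSD1 (encoded by KDM1A) removes methyl groups from lysine 4 of histone H3, and DOT1L adds them to lysine 79. Each library held 15015039 to 20030093 gene counts, and 21991 to 26481 genes had at least 1 count.

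The comparison of the outer gates asked which genes differ between cells at the ends of the dye range. By camera, lists of p53 targets, collagen and matrix, lysosomal, and NRF2 and iron stress genes were higher in high than in low dye cells, and lists of DNA replication and mitosis genes were lower. Of these calls only those of p53 targets and of collagen and matrix held with an estimated correlation. All 9 lists that camera called between the outer gates passed fry. The largest increase under the naming rule was that of GPNMB, a lysosomal and melanosomal membrane glycoprotein (ENSG00000136235, chromosome 7 from 23235967 to 23275108, GRCh38), at 27.2 ± 12.7 CPM in high dye and 1.62 ± 0.490 CPM in low dye (SD, n = 4 each), or 16.8-fold. GDF15, a stress-induced cytokine (ENSG00000130513, chromosome 19 from 18374731 to 18389176), stood at 222 ± 120 against 24.1 ± 6.76 CPM. SPP1, the secreted matrix protein osteopontin (ENSG00000118785, chromosome 4 from 87975650 to 87983426), stood at 256 ± 158 against 33.0 ± 11.2 CPM. Log2 fold changes were 4.07 ± 0.43 (SE) for GPNMB, 3.21 ± 0.45 for GDF15 and 2.96 ± 0.50 for SPP1, with adjusted p of 8.1e-05, 3.8e-04 and 0.0013 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other genes named by rule at this end were TMEM132B, SCG5, IGFBP5, SPATA18, LURAP1L, ATF3, COL11A1, ITGA11 and GASK1B, with log2 fold changes from 3.10 (TMEM132B) down to 2.22 (GASK1B). As the naming rule required, each of these 12 genes was higher in high dye in 4 of 4 same-numbered pairs.

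Of the 26 p53 targets measured, 23 rose in high dye and 3 did not pass the test, with a median log2 fold change of 0.98 over the list. CDKN1A, the p21 inhibitor of cyclin-dependent kinases (ENSG00000124762, chromosome 6 from 36676460 to 36687339), reached 866 ± 333 CPM in high dye and 187 ± 47.1 CPM in low dye, a log2 fold change of 2.21 ± 0.30. BTG2, an antiproliferative factor, changed by 3.08 ± 0.39, ZMAT3 by 1.29 ± 0.16 and PHLDA3 by 1.16 ± 0.15 on the log2 scale. Among 8 cyclin-dependent kinase inhibitors 3 rose and 2 fell, CDKN2B by 1.13 ± 0.20 and CDKN2A by 0.49 ± 0.12 upwards, while CDKN3 was at -0.92 ± 0.26, and the list as a whole did not pass (camera adjusted p = 0.254). The p53 list passed camera at an adjusted p of 8.1e-25 and also with an estimated correlation (adjusted p = 0.0439), and 23 members passed when adjusted over the list alone.

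Matrix and lysosomal genes formed the next groups. Of 24 collagen and matrix genes 11 rose and 0 fell (median 0.51, camera adjusted p = 6.1e-06, adjusted p = 0.0226 with an estimated correlation, 13 adjusted over the list alone). They included COL11A1 at 2.30 ± 0.55, COL1A2 at 0.65 ± 0.16, COL5A1 at 0.65 ± 0.10 and fibronectin (FN1) at 0.54 ± 0.11, FN1 being the most abundant of the 4 at 16100 ± 2791 CPM in high dye. Of 26 lysosomal genes 17 rose and 0 fell (median 0.42, camera adjusted p = 1.1e-11, adjusted p = 0.0667 with an estimated correlation, 19 adjusted over the list alone), among them prosaposin (PSAP) at 0.83 ± 0.15 and the protease CTSA at 0.58 ± 0.11. Of 18 NRF2 and iron stress genes 10 rose and 0 fell (median 0.57, camera adjusted p = 2.6e-07, adjusted p = 0.298 with an estimated correlation, 11 adjusted over the list alone). The ferritin chains FTL and FTH1 changed by 1.33 ± 0.23 and 1.44 ± 0.26, and the autophagy receptor SQSTM1 by 1.55 ± 0.27. FTL stood at 2202 ± 755 against 875 ± 131 CPM.

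The secreted and inflammatory list had 6 members up and 1 down of 25 (median 0.36, camera adjusted p = 0.0347, adjusted p = 0.366 with an estimated correlation, 6 up and 2 down adjusted over the list alone). SPP1, the protease MMP3 (2.08 ± 0.37), the growth factor binding protein IGFBP5 (2.51 ± 0.48) and the protease inhibitor TIMP1 (0.36 ± 0.07) were among the 6. The integrated stress list had 6 up and 1 down of 20 (median 0.56, camera adjusted p = 0.0117, adjusted p = 0.298 with an estimated correlation, 9 up and 2 down adjusted over the list alone). DDIT3 changed by 1.25 ± 0.25, SESN2 by 1.77 ± 0.44, ATF3 by 2.41 ± 0.65 and CHAC1 by 1.90 ± 0.52.

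Genes of DNA replication were lower in high dye almost without exception, with 40 of 42 measured S phase genes falling, 41 of them when adjusted over the list alone (median -0.85). The largest drop under the naming rule was that of ORC1, a subunit of the origin recognition complex (ENSG00000085840, chromosome 1 from 52372829 to 52404459), at 14.99 ± 3.99 CPM in high dye and 37.1 ± 3.91 CPM in low dye, a log2 fold change of -1.30 ± 0.17. The replication licensing factor CDT1 stood at -1.14 ± 0.19, the helicase subunit MCM2 at -1.11 ± 0.22, MCM10 at -1.08 ± 0.22, the checkpoint adaptor CLSPN at -1.12 ± 0.19 and DTL at -1.13 ± 0.17. SLC7A2, CDCA7, SAPCD2, ZNF367, SLFN11 and FAM111B complete the 12 genes, with values from -1.30 for SLC7A2 to -1.19 for FAM111B. Each of the 12 was lower in all 4 pairs, as the rule required. In the G2 and mitosis list 30 of 52 genes fell and 0 rose, 42 when adjusted over the list alone (median -0.55), for example CDC20 at -0.97 ± 0.21 and NEK2 at -0.84 ± 0.17. Of the fixed proliferation genes MKI67 changed by -0.87 ± 0.23, CENPF by -0.68 ± 0.20 and ASPM by -0.70 ± 0.19, and TOP2A had -0.15 ± 0.20, not past the threshold. Of 22 MYC and ribosome biogenesis genes 8 fell and 0 rose (median -0.24), including NOLC1 at -0.39 ± 0.08 and DKC1 at -0.39 ± 0.08. Camera gave adjusted p of 1.2e-37, 2.4e-20 and 1.1e-05 for the S phase, G2 and mitosis, and MYC lists, and these calls were lost with an estimated correlation (adjusted p = 0.102, 0.298 and 0.298).

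Most lists of other cell types and programs did not pass the test between the outer gates. HOX (22 genes, median 0.07), epithelial (8 genes, 0.02), endothelial (5 genes, 0.72), melanocyte and Schwann cell (3 genes, 0.56), interferon (18 genes, 0.41), nuclear oxidative phosphorylation (29 genes, 0.01) and mitochondrially encoded (13 genes, -0.01) lists had 0 members past the threshold and did not pass camera. The same test was not passed by the mesenchymal transcription factor (1 up of 17), pluripotency (1 up of 4, SALL4), neuronal (2 up of 12, VGF and UCHL1), immediate early (2 up of 15), ribosomal protein (3 up of 46), contractile (2 up and 1 down of 18), TGF-beta and YAP target (2 down of 18), cholesterol (1 up and 2 down of 19) and glycolysis and hypoxia (4 up and 4 down of 22) lists. Only 2 myeloid and erythroid genes were measured, and that list was not tested. Of 17 replication-dependent histone genes 6 were higher and 1 was lower (median 0.81, camera adjusted p = 0.0557) and H2AC6 was the most abundant in high dye at 16.1 against 4.65 CPM. In the 4 high dye libraries left out in turn that median ranged from 0.51 without replicate 3 to 0.99 without replicate 1. The median (-0.20) and the test (upwards) of the pluripotency list differed in sign. With the replicate block the contractile (2.9e-05), neuronal (0.0012), immediate early (0.0061) and histone (0.0271) lists also passed camera, which brought the number of lists from 9 to 13, of which 5 held with an estimated correlation against 2 without the block. Of the 4 added lists only the neuronal one held (adjusted p = 0.0465 with an estimated correlation).

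Among the reprogramming and chromatin genes fixed in advance, KDM1A stood at 134 ± 19.1 CPM in high dye and 173 ± 6.77 CPM in low dye, a log2 fold change of -0.37 ± 0.10 (edgeR adjusted p = 0.0138). DOT1L (-0.25 ± 0.12), MYC (-0.19 ± 0.07), KLF4 (0.10 ± 0.19), POU5F1 (-0.39 ± 0.33) and SOX2 (-0.37 ± 0.30) did not pass. TERT, present at 1314 ± 621 CPM in high dye and 886 ± 545 CPM in low dye, did not pass either (0.57 ± 0.46, adjusted p = 0.42). With the replicate block TERT (adjusted p = 0.0073, higher in 3 of 4 pairs), DOT1L (0.0358) and MYC (0.0159) passed.

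Between high and low dye, 2589 of 14592 genes were called by edgeR, 1370 higher and 1219 lower in high dye, and 403 higher and 84 lower genes changed at least 2-fold. With the replicate block the count was 5433 (2891 higher, 2542 lower), including all 2589. The blocked fit called 42 S phase, 48 G2 and mitosis and 12 MYC genes lower, and 24 p53 targets, 21 lysosomal, 18 collagen and 16 NRF2 and iron stress genes higher, with 12 up and 3 down in the integrated stress list and 9 up and 3 down in the secreted list. The number rested in part on single libraries, at 1255 without high dye replicate 3 and 1519 without high dye replicate 1, and it was 1497 when only the 8 compared libraries were fitted.

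The level of the cell cycle lists in each library was compared between the outer gates. The mean log2 CPM of the S phase list was 5.26 ± 0.45 in high dye and 6.16 ± 0.11 in low dye (SD, n = 4 each), lower in 4 of 4 pairs. The difference of -0.90 gave p = 0.0286 in an exact permutation test over 70 assignments (two-sided), the smallest p this design allows. For the G2 and mitosis list the means were 6.44 ± 0.47 and 7.06 ± 0.11, a difference of -0.61 with an exact p = 0.0286, and adjustment over the 2 lists left both p unchanged. Within the 4 pairs, sign flips gave an exact p = 0.125 for each list, again the smallest possible, so sign flips of 4 pairs could not reach 0.05. Leaving out any 1 low dye library also ended these calls (exact p = 0.0571 for S phase and 0.0857 to 0.143 for G2 and mitosis). The differences then stayed at -0.93 to -0.86 for S phase and -0.64 to -0.57 for G2 and mitosis. Without any 1 high dye library the exact p stayed at 0.0286 for both lists.

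**Figure D1:**
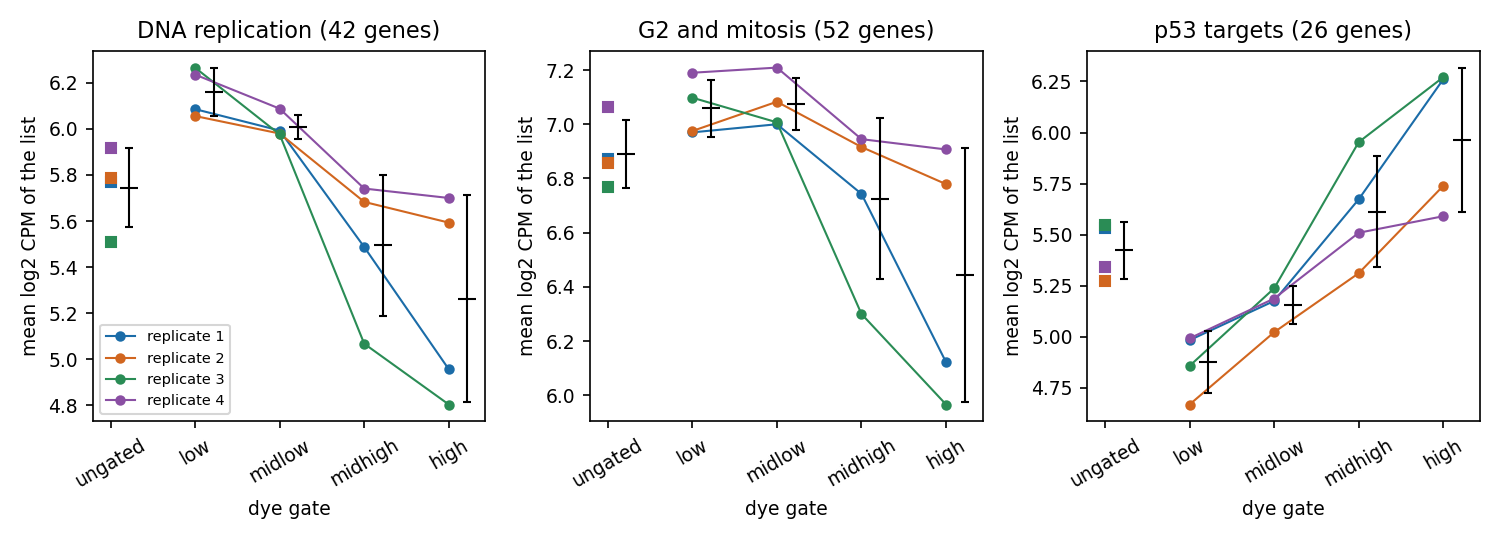
Mean log2 CPM of the S phase (42 genes), G2 and mitosis (52 genes) and p53 target (26 genes) lists in each sort library, against the dye gate, with lines joining the gates of 1 replicate number, squares for ungated libraries, and black bars for the mean and SD of 4 libraries. The S phase level in high dye lay between 4.80 (replicate 3) and 5.70 (replicate 4), below the low dye range of 6.06 to 6.27.

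The trend asked which genes had a straight-line slope over the 4 gates. Whether a gene changed at every step was not tested. In edgeR's quasi-likelihood test 3784 of 14419 genes had a trend, 2012 rising and 1772 falling towards high dye, and with the replicate block 6317 (3331 rising, 2986 falling), including all 3784. The steepest rise under the naming rule belonged to GPNMB at 1.42 ± 0.12 log2 units per gate step, followed by GDF15 (1.12 ± 0.14), TMEM132B (1.07 ± 0.20), SPP1 (1.03 ± 0.14) and IGFBP5 (0.89 ± 0.17). The steepest falls under that rule were those of SLC7A2 (-0.46 ± 0.09), ORC1 (-0.46 ± 0.05), CDCA7 (-0.45 ± 0.06), ZNF367 (-0.43 ± 0.07) and FAM111B (-0.43 ± 0.08). CDKN1A mRNA averaged 187, 272, 520 and 866 CPM from low to high dye. Of the lists, 41 of 42 S phase and 39 of 52 G2 and mitosis genes fell, while 22 of 26 p53 targets, 17 of 26 lysosomal, 13 of 24 collagen and matrix and 11 of 18 NRF2 and iron stress genes rose. In the other lists that passed camera, integrated stress had 9 up and 2 down, secreted and inflammatory 6 up and 2 down, replication-dependent histone 8 up and 1 down, and MYC and ribosome biogenesis 9 down. All 10 list calls were lost with an estimated correlation, the lowest being adjusted p = 0.0774 with an estimated correlation for the p53 and the collagen lists. All 10 lists passed fry. With the replicate block 15 lists passed, the contractile, TGF-beta and YAP target, neuronal, interferon and immediate early lists in addition, and 0 held with an estimated correlation. Without high dye replicate 3 the trend count was 2514.

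**Figure D2:**
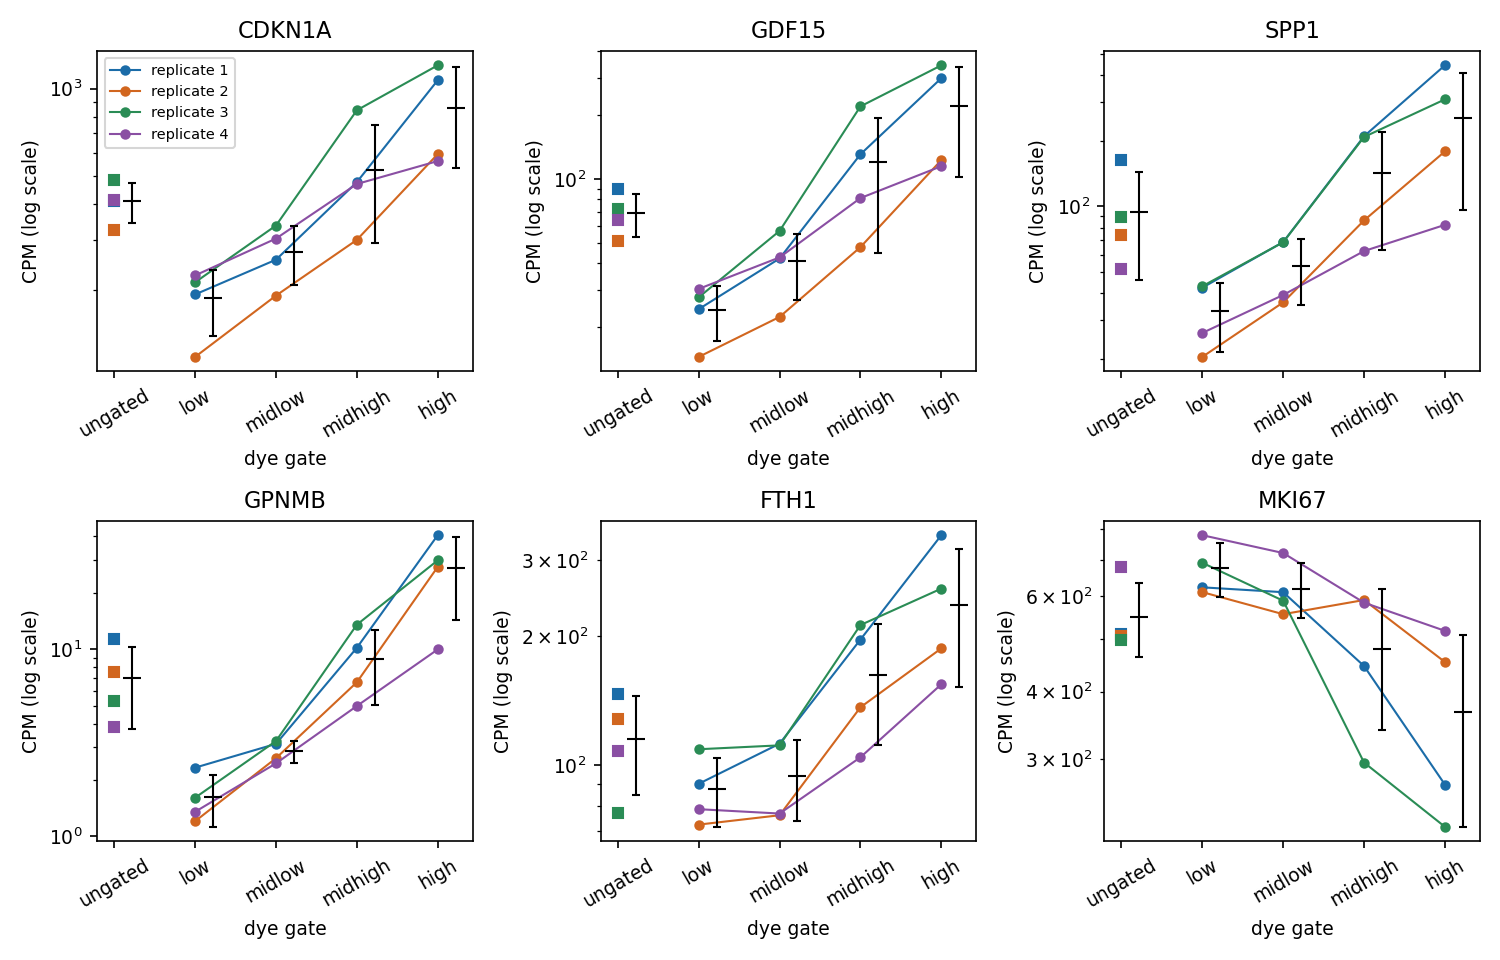
CPM (log scale) of 6 genes in each sort library against the dye gate, with lines joining the gates of 1 replicate number, squares for ungated libraries, and black bars for the mean and SD of 4 libraries. CDKN1A, GDF15, SPP1, GPNMB and FTH1 were higher, and MKI67 was lower, in high than in low dye in every replicate number.

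The inner gates were compared to ask whether cells nearer the middle of the dye range also differed. Without the block, the lists called at the outer gates passed here in the same direction, except integrated stress, and no single gene was called. Their medians were smaller than at the outer gates, a difference that was not tested. The p53 target list (median 0.43, camera adjusted p = 8.5e-12), the lysosome list (0.23, 5.8e-08), the collagen and matrix list (0.33, 3.4e-06), the NRF2 and iron stress list (0.29, 3.6e-05) and the secreted list (0.21, 0.0405) were higher in midhigh dye. The S phase (-0.50, 9.6e-33), G2 and mitosis (-0.34, 1.4e-17) and MYC (-0.15, 2.4e-04) lists were lower. The collagen call alone held with an estimated correlation (adjusted p = 0.0152), and the other 7 were lost (lowest adjusted p = 0.201 with an estimated correlation). Of the 8 lists 1 passed fry. Adjusted over the list alone, 36 S phase genes fell, and 9 p53 targets, 2 lysosomal genes and 1 collagen gene rose. GDF15 had 1.55 ± 0.42, SPP1 1.41 ± 0.48, CDCA7 -0.75 ± 0.19 and ORC1 -0.72 ± 0.17 on the log2 scale, none past the threshold. edgeR called 0 of 14592 genes, 1891 had an unadjusted p under 0.05, and the DESeq2 Wald test called 122. With the replicate block edgeR called 1574 (805 higher, 769 lower in midhigh dye), GDF15 (adjusted p = 0.0011) and ORC1 (0.0039) among them, and the integrated stress (0.0027), contractile (2.8e-05) and neuronal (0.0155) lists passed camera as well, calls that were lost with an estimated correlation (adjusted p = 0.275, 0.236 and 0.146). With the block 11 lists passed camera against 8 without it, and 2 against 1 held with an estimated correlation. The median and the test differed in sign for the cholesterol, glycolysis and hypoxia, and oxidative phosphorylation lists.

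High dye cells were compared with ungated cells to ask how the upper end of the dye range differs from the whole population. Without the replicate block edgeR called 1 gene, against 1107 with it. In the fit without the block 8 lists passed camera, none of which held with an estimated correlation or passed fry. The S phase (median -0.43), G2 and mitosis (-0.41), p53 target (0.48), NRF2 and iron stress (0.48), integrated stress (0.43), lysosome (0.23), replication-dependent histone (0.60) and ribosomal protein (0.05) lists were the 8. Their adjusted p ran from 1.1e-28 for S phase to 0.0423 for ribosomal proteins. The lowest of the lost calls was that of p53 targets (adjusted p = 0.151 with an estimated correlation). Adjusted over the list alone, 18 p53 targets, 6 NRF2 and iron stress genes and 2 lysosomal genes rose and 12 S phase genes fell. The gene called without the block was ASTN2, a neuronal membrane protein gene named after its values were seen because it lay under 10 CPM. It stood at 6.85 ± 0.780 against 3.44 ± 0.252 CPM (log2 fold change 0.99 ± 0.14, edgeR adjusted p = 0.0177, higher in 4 of 4 pairs). GPNMB had 1.96 ± 0.37, GDF15 1.69 ± 0.42 and CDKN1A 1.09 ± 0.29 on the log2 scale without passing, each higher in 4 of 4 pairs, and all 3 passed with the replicate block (adjusted p = 4.2e-05, 6.4e-04 and 8.7e-04). The library labelled ungated replicate 3 had 28 genes over 2-fold outside the range of the 4 gates of its own number, against 0 in ungated replicates 1, 2 and 4. Of 14592 genes 1 was called and 1543 had an unadjusted p under 0.05. The DESeq2 Wald test called 18, and the replicate block 1107 (534 higher, 573 lower), or 542 without ungated replicate 3. With the block 14 lists passed camera against 8 without it, and 0 held with an estimated correlation. The median and the test of the cyclin-dependent kinase inhibitor and pluripotency lists differed in sign. Without ungated replicate 3 the ribosomal protein list no longer passed (adjusted p = 0.0597), and the secreted, collagen and neuronal lists did (0.0350, 0.0266 and 0.0479), calls that were lost with an estimated correlation (adjusted p = 0.463, 0.190 and 0.190). Adjusted over the list alone, 31 S phase genes then fell and 3 NRF2 and iron stress genes and 5 lysosomal genes rose. The call of ASTN2 ended without ungated replicates 1, 2 or 4 or high dye replicates 1, 2 or 3, and without high dye replicate 4 the count was 6.

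Low dye cells were compared with ungated cells to ask how the lower end of the dye range differs from the whole population. In the fit without the replicate block, only 1 of the 7 lists that passed camera held with an estimated correlation. No single gene was called higher in low dye in that fit, whereas with the block 524 genes were higher and 1051 lower. Camera passed for the S phase (median 0.43, adjusted p = 1.0e-22), G2 and mitosis (0.18, 2.6e-05) and MYC (0.18, 2.8e-09) lists upwards. It passed downwards for the p53 target (-0.39, 1.3e-14), lysosome (-0.21, 6.0e-07), collagen and matrix (-0.33, 4.3e-07) and interferon (-0.79, 2.1e-05) lists. Collagen alone held with an estimated correlation (adjusted p = 0.0082), and the other 6 were lost (lowest adjusted p = 0.213 with an estimated correlation). Of the 7 lists 4 passed fry. Adjusted over the list alone, 16 S phase and 5 MYC genes rose, and 11 p53 targets, 7 collagen, 2 lysosomal and 2 interferon genes fell. The interferon list was far higher in ungated replicate 3 (mean log2 CPM 3.56) than in the other ungated libraries (1.83 to 2.65), and without it the median was -0.27 (adjusted p = 0.0396, and 0.834 with an estimated correlation). Leaving that library out also left 1 S phase, 1 collagen, 1 lysosomal, 0 MYC and 0 interferon genes past the threshold when adjusted over the list alone, and brought the NRF2 and iron stress list past camera (adjusted p = 0.0014, lower in low dye), a call lost with an estimated correlation (adjusted p = 0.791). With the block 11 lists passed camera against 7 without it, 2 of them with an estimated correlation. The median and the test of the TGF-beta and YAP target and the mesenchymal transcription factor lists differed in sign. The 11 genes called without the block were all lower in low dye. Those named by rule were CLIP3 (-0.96 ± 0.16), MXD4, a MAX-binding repressor (-0.95 ± 0.16), CCNG2, an atypical cyclin (-0.79 ± 0.14), TNFRSF21 (-0.68 ± 0.11) and ARMCX2 (-0.58 ± 0.10). Their edgeR adjusted p ran from 0.0241 to 0.0314, and the rule required the same direction in all 4 pairs. Of 14592 genes 1898 had an unadjusted p under 0.05, the DESeq2 Wald test called 188, and the replicate block 1575 (524 higher, 1051 lower), or 899 without ungated replicate 3. The edgeR count was 0 without ungated replicates 2 or 3 or low dye replicates 3 or 4, 5 without low dye replicates 1 or 2, and 36 without ungated replicate 4.

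In the fit without a block, LSD1 inhibition raised 16 genes and lowered 0 of 14002. With the replicate block, which left 1 residual degree of freedom, 2242 genes were called, 1274 higher and 968 lower. In simulated data that blocked fit made 31 false calls among 142, and the fit without the block 15 among 109. Those data held no replicate effect, so they cannot show how the block performs on paired libraries. The values below come from the fit without the block. TM7SF2, which encodes a sterol reductase (ENSG00000149809, chromosome 11 from 65111845 to 65116384), rose from 4.23 ± 0.166 to 26.9 ± 2.17 CPM (SD, n = 2 each), a log2 fold change of 2.66 ± 0.16. The insulin-like growth factor binding protein gene IGFBP3 (chromosome 7 from 45912245 to 45921874) rose from 83.0 ± 1.69 to 273 ± 49.8 CPM, a change of 1.72 ± 0.15, and the smooth muscle actin gene ACTA2 (chromosome 10 from 88935074 to 88991339) from 53.5 ± 2.67 to 121 ± 0.321 CPM, a change of 1.17 ± 0.11. REEP2 (1.81 ± 0.17), the proton pump subunit gene ATP6V0E2 (1.70 ± 0.13), SYNGR2 (1.67 ± 0.16), SQOR (1.41 ± 0.14), the secreted chaperone gene CLU (1.35 ± 0.11), MYEF2 (1.30 ± 0.12), the Wnt ligand gene WNT16 (1.13 ± 0.11), the sodium leak channel gene NALCN (1.04 ± 0.10) and CYFIP2 (1.02 ± 0.11) complete the 12 named by rule. ABCA3 (4.26 ± 0.24), PPP1R9A (3.22 ± 0.35), PLAAT3 (2.23 ± 0.23) and CHRNB1 (2.18 ± 0.19) lay under 10 CPM on average and were named after their values were seen. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.0103 to 0.0472, and all 16 genes were higher in both same-numbered pairs. KDM1A itself (-0.09 ± 0.14), TERT (-0.48 ± 0.61), SOX2 (0.50 ± 0.24) and CDKN1A (0.18 ± 0.23) did not pass, although TERT was lower in both same-numbered pairs (678 to 481 and 1994 to 1417 CPM).

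Among the lists, G2 and mitosis (median -0.21, camera adjusted p = 1.0e-07), S phase (-0.17, 1.2e-04) and interferon (-0.54, 1.0e-07) were lower under LSD1 inhibition. Collagen and matrix (0.29, 1.9e-06), epithelial (0.46, 2.9e-06), contractile (0.07, 8.9e-06), secreted and inflammatory (0.03, 0.0070) and NRF2 and iron stress (0.11, 0.0492) were higher. All 8 list calls were lost with an estimated correlation (lowest adjusted p = 0.775 with an estimated correlation), and 0 of the 8 lists passed fry. Single members that passed were IGFBP3 among the secreted and ACTA2 among the contractile genes. Adjusted over the list alone, 5 collagen and 5 contractile genes, 3 epithelial genes and 3 secreted genes rose, and 4 interferon genes and 1 collagen gene (VCAN, -0.54 ± 0.12) fell. Values that did not pass over all genes included the epithelial adhesion gene EPCAM (2.36 ± 0.33, 0.557 to 2.89 CPM), the keratin KRT19 (2.27 ± 0.47), COL3A1 (0.83 ± 0.15), LMOD1 (1.07 ± 0.16) and IFIT1 (-1.60 ± 0.44, with controls at 19.7 ± 11.6 CPM). The median and the test differed in sign for the TGF-beta and YAP target, mesenchymal transcription factor, pluripotency, ribosomal protein and mitochondrially encoded lists. Each arm had 2 libraries and the controls were of different kinds. In edgeR 950 genes had an unadjusted p under 0.05, the DESeq2 Wald test called 116, no gene was called when no filter was set, and leaving out DMSO replicate 1, no drug replicate 2, LSD1 inhibition replicate 1 or LSD1 inhibition replicate 2 gave 232, 331, 108 and 131 genes, each time including all 16.

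**Figure D3:**
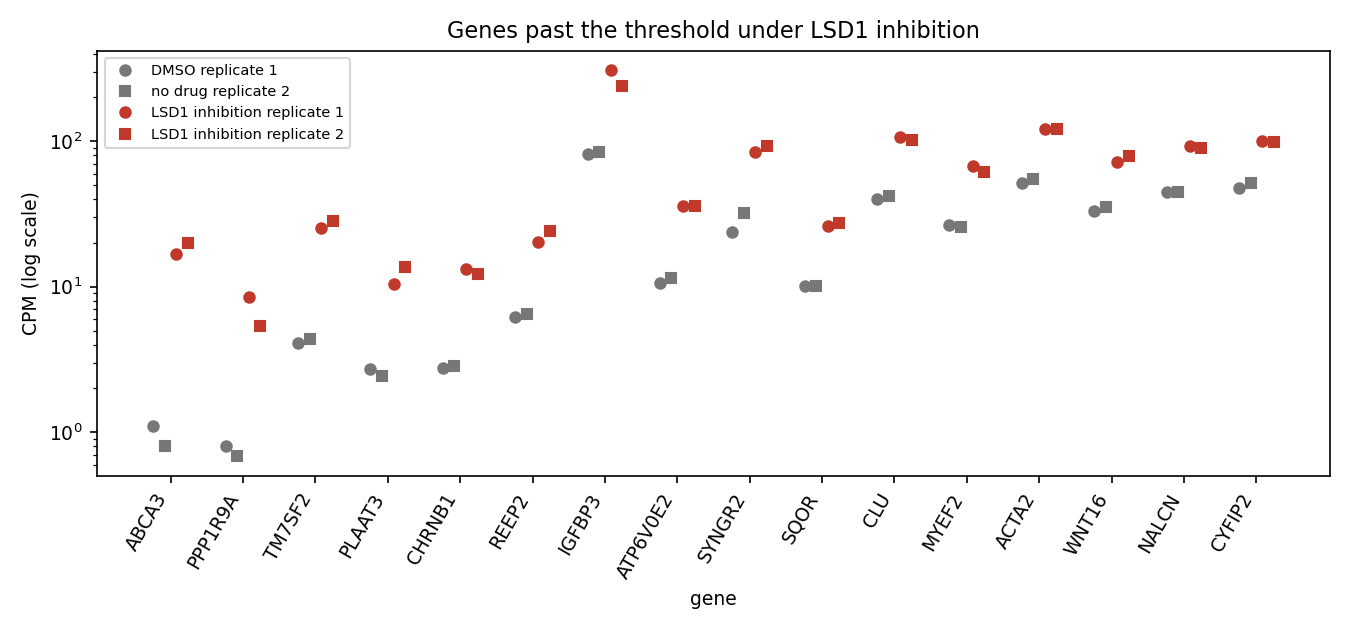
CPM (log scale) of the 16 genes past the threshold under LSD1 inhibition, with 1 point per library (gray, DMSO and no drug; red, LSD1 inhibition; circles, replicate 1; squares, replicate 2). Both LSD1 inhibition libraries lie above both controls for each gene, as for ABCA3 at 16.9 and 20.1 against 1.11 and 0.808 CPM.

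DOT1L inhibition was measured in 1 library against 1 DMSO library, so its values carry no error and no test. At 10 CPM or more in either library, 56 of 9194 genes were at least 2-fold higher and 13 at least 2-fold lower. The largest ratios belonged to the hair keratin KRT81 (2.45 to 13.2 CPM, 39 and 230 counts, log2 ratio 2.38), the glutamate receptor subunit GRIK2 (2.32), PLPPR4 (2.17), the prostaglandin E synthase PTGES (2.17), the decoy receptor TNFRSF11B (2.12), SEMA3B (2.01), the proteoglycan lumican LUM (2.01), KRT19 (1.94), CEMIP (1.86) and SHISA2 (1.82). The lowest belonged to ESM1 (110 to 44.1 CPM, -1.32), the transcription factor genes SOX21 (-1.31), PRRX1 (285 to 130 CPM, -1.13), MEIS1 (-1.09) and TBX3, and to TRHDE (-1.11), RFX8 (-1.05), SCUBE3 (-1.05), MLLT11 (-1.02) and BMAL2 (-1.01). In the HOX list, which includes the cofactor MEIS1, 15 of 18 genes were below 0 and the median was -0.67, lower than all of 10000 random lists matched on expression (central 95% from -0.15 to 0.22). HOXA10 (-0.97) and HOXA11 (-0.94) were among the lowest, and 3 genes were above 0. Random lists do not carry the correlation between members of a real list, so their central 95% may be too narrow. The rank is a description without a test.

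S phase (median -0.35), G2 and mitosis (-0.27) and p53 target (-0.19) genes were also below the central 95% of random lists under DOT1L inhibition, with 42 of 42 S phase genes at or below 0. The neuronal (0.76), epithelial (0.45), secreted (0.29), TGF-beta and YAP target (0.28), NRF2 and iron stress (0.27), mitochondrially encoded (0.25), collagen and matrix (0.21), contractile (0.21), lysosome (0.17) and ribosomal protein (0.05) lists lay above the central 95% of random lists. As for HOX, these positions are descriptions, since random lists do not carry the correlation between members. They do not separate the drug from other differences between the libraries. NEFL, a neurofilament gene, went from 19 to 137 counts (2.61), IGFBP3 from 1332 to 4764 (1.71), COL3A1 from 1074 to 2899 (1.30), ITGA11 from 432 to 1182 (1.32) and GPNMB from 72 to 202 (1.34). DOT1L mRNA (-0.06), KDM1A (-0.12) and TERT (-0.14) had ratios near 0. The DMSO library was, of all 25 libraries, closest to the library labelled ungated replicate 3 of the sort set (r = 0.996 across genes).

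**Figure D4:**
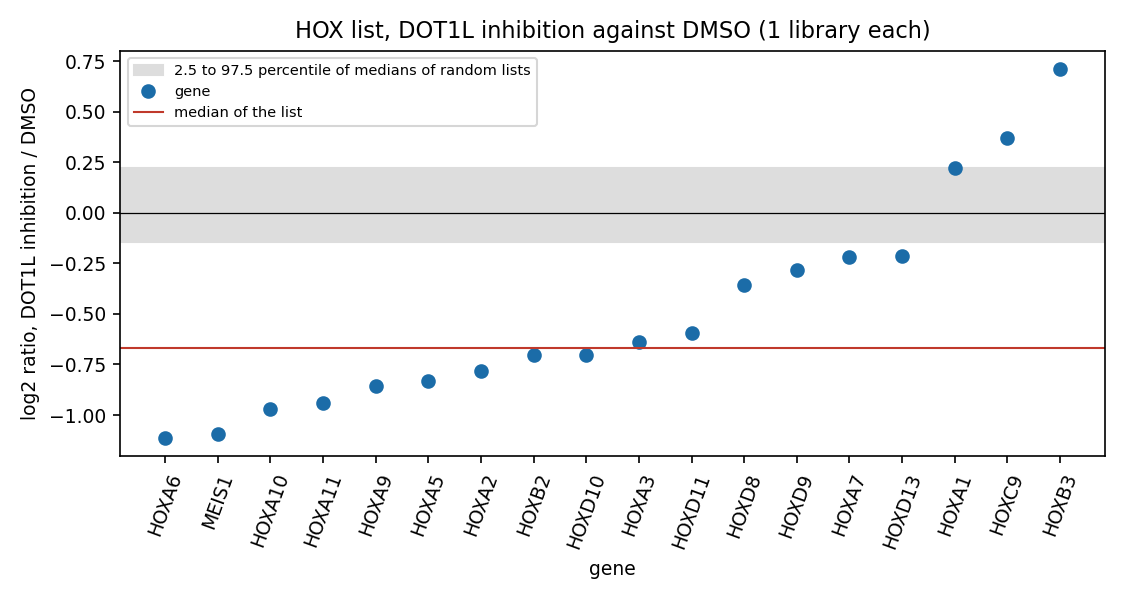
Log2 ratio of CPM, DOT1L inhibition over DMSO with 1 library each, for 18 genes of the HOX list (points). The red line is the median of the list (-0.67), and the gray band holds the central 95% of the medians of 10000 random lists (-0.15 to 0.22).

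Across genes, which are not independent replicates, 3 relations between changes were computed. Changes under LSD1 inhibition correlated with those between high and low dye across 13821 genes at Pearson r = 0.22 and Spearman rho = 0.24. Of 35 splits of the 8 high and low dye libraries 3, the real one included, had an absolute r as large (highest other 0.23), a share of 0.0857, and these splits do not keep the replicate pairs. The changes of LSD1 inhibition replicate 2 and of DOT1L inhibition, which share no library, correlated at r = 0.27 and rho = 0.23 over 12866 genes. The LSD1 inhibition replicates correlated with each other at r = 0.58 and had the same sign in 68.8% of genes. No p is given for the correlations between drug ratios because each ratio rests on 1 library per arm.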

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

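The tests of handling, of a swap and of another culture for ungated replicate 3, and the tests of RNA from other tissues and of genomic DNA for high dye replicate 3, were chosen only after the result was seen. The tests of depth, of poly(A) selection and of single libraries were written before their own results were seen.

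Each group of 4 libraries was searched for 1 value far from the other 3 with Dixon's ratio. Of 85 such tests 5 passed a level at which chance gives about 1 in 20. Low dye replicate 2 had 18914812 gene counts (18.9 M), against 16005953 to 16383034 in the other low dye libraries. Mitochondrial genes took 2.39% of the counts in high dye replicate 4, against 2.71% to 2.77%. The S phase level was 6.09 in midlow dye replicate 4, against 5.98 to 5.99 mean log2 CPM. The interferon level was 2.75 in midlow dye replicate 2, against 1.70 to 1.76, and it was also the highest of its gate in low (2.43), midhigh (2.83) and high dye (2.67 mean log2 CPM) replicate 2. MKI67 reached 679 CPM in ungated replicate 4, against 499 to 512 CPM in the other ungated libraries.

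The library labelled ungated replicate 3 had 28 genes (19 above, 9 below) over 2-fold outside the range of the 4 gates of its own number, of 8914 genes at 10 CPM or more, for instance the interferon-induced IFI6 at 48.8 CPM against 9.02 to 14.3 CPM and the Wnt antagonist SFRP1 at 485 against 156 to 175 CPM. Handling that sets all ungated apart from gated cells was excluded, because ungated replicates 1, 2 and 4 had 0 such genes. A swap with a drug library was excluded, because 0 of the 5 drug libraries had a gate of number 3 as the closest library. Handling of ungated replicate 3 alone was not tested. Its closest library was DMSO replicate 1 (r = 0.996, against at most 0.981 within its own number), with 2 of 8947 genes 2-fold apart and a chi-square per degree of freedom of 4.07. Of all 300 pairs of libraries 5, this one included, had a chi-square as low (lowest other 3.45). Cells of another culture and a single wrong label may each give such a library, and these cannot be told apart here. No biological explanation was tested.

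High dye replicate 3 had 26481 genes with a count, the most of the 25 libraries. Greater depth was excluded, since 25989 genes remained after thinning all libraries to 15015039 counts, against at most 23688 in the 23 libraries other than it and midhigh dye replicate 3. RNA from other tissues stayed open, at 4.01 CPM over 46 marker genes against up to 3.62 CPM in other sort libraries (high dye replicate 4, the library with the fewest genes) and 5.72 and 4.65 CPM in the drug libraries DOT1L inhibition and LSD1 inhibition replicate 1. Genomic DNA or unspliced RNA stayed open too, with 6.33% of reads assigned to no feature against up to 7.72% in other libraries. The feature type used for counting is not stated here, so this share may or may not hold intronic reads. RNA from other tissues and genomic DNA or unspliced RNA might each add such low counts, and they cannot be told apart. No biological explanation was tested.

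Replication-dependent histone transcripts, most of which lack a poly(A) tail, had a median log2 fold change of 0.81 in high against low dye while S phase genes fell. The list was mixed, since H2AC6 rose (1.80 ± 0.37) and H2AC11 fell (-0.74 ± 0.21). Some members had few counts, such as H3C8 at 0.471 CPM in high and 0.726 CPM in low dye. Weaker poly(A) selection would raise other RNAs without a tail, and the median of 9 of these was -0.20 with a bootstrap SE of 0.21. Only 1 of the 9 reached 2 CPM, so the value does not decide, and weaker selection could still have a part and cannot be told apart from other causes. The counts of 1 library were excluded as the sole cause, since the lowest median with 1 high dye library left out was 0.51, without replicate 3. No biological explanation was tested.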

How the results depend on the processing

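The fits without ungated replicate 3 or without high and midhigh dye replicate 3, and the left-out libraries and sign flips for list levels, were chosen only after the result was seen. Between high and low dye the count of 2589 genes became 487 at a log2 fold change of at least 1, 5433 with the replicate block, 1497 with only the 2 groups fitted, 1255 to 2965 with 1 library left out, and 1409 without high and midhigh dye replicate 3. For midhigh against midlow dye 0 genes became 99 without a filter, 122 with DESeq2 and 1574 with the block. For high dye against ungated cells 1 gene became 0 at a log2 fold change of at least 1 or with only the 2 groups, 25 without a filter, 18 with DESeq2, 1107 with the block, 542 with the block and without ungated replicate 3, and 0 to 6 with 1 library left out. For low dye against ungated cells 11 genes became 4 at that fold change, 177 without a filter, 188 with DESeq2, 1575 with the block, 0 with only the 2 groups, 899 with the block and without ungated replicate 3, and 0 to 36 with 1 library left out. For the trend 3784 genes became 33 at 1 log2 unit per step, 6317 with the block, 2322 without high and midhigh dye replicate 3, and 2514 to 4149 with 1 library left out. For LSD1 inhibition 16 genes became 0 without a filter, 116 with DESeq2, 2242 with a block that left 1 residual degree of freedom and whose simulated calls were false in 31 of 142, and 108 to 331 with 1 library left out, where a lone library was assumed to vary like the others. Of 50 list calls 4 held with an estimated correlation and 24 with fry, which passed 30 lists in all. The S phase difference of -0.90 had an exact p = 0.125 by sign flips and ranged from -1.04 to -0.74 with 1 library left out, and the G2 and mitosis difference of -0.61 had an exact p = 0.125 and ranged from -0.77 to -0.46. The block takes out variation shared by a replicate number. In the fit of all 20 sort libraries it lowered edgeR's coefficient of variation between libraries from 16.2% to 7.74%. For LSD1 inhibition it also left 1 residual degree of freedom, so the rise cannot be put down to shared variation alone. What caused the other moves was not tested. For high against low dye 1 of 35 splits of the 8 libraries called as many genes, the real one with 2589 (highest other 1). For the trend (real 3784) only 1 of 100 draws called as many, the real one, over all libraries (highest other 531). The same held within replicate numbers (highest other 2731, in an order close to the reversed gates). A share of 1 in 100 is the smallest these draws can give, so chance was unlikely at a level of 0.05 but not excluded. Against ungated cells 1 of 35 splits called as many for high dye (real 1, highest other 0) and for low dye (real 11, highest other 0). Only 8 of the 35 splits part all 4 pairs, too few for a share under 0.05, and the highest other among these was 1 for high against low dye and 0 against ungated cells. For midhigh against midlow dye the real split called 0 genes, so that 35 of 35 splits called as many (highest other 0) says nothing about chance. Depth of 15015039 to 20030093 counts limits genes under about 1 CPM, and 4 libraries per group limit the exact permutation test to p = 0.0286.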

Other observations

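No test was run for the values in this part, which were chosen only after the result was seen. TERT mRNA in low dye stood at 1641, 572, 934 and 402 CPM in replicates 1 to 4 and in high dye at 1619, 766, 2004 and 813 CPM, so it was higher in high dye in replicates 2, 3 and 4. In the drug set it was 678 CPM with DMSO, 617 CPM with DOT1L inhibition and 481 CPM with LSD1 inhibition as replicate 1, and 1994 CPM with no drug and 1417 CPM with LSD1 inhibition as replicate 2. Ungated replicate 3 had 730 CPM, below the 934 to 2004 CPM of the gates of its number. The high dye libraries with the lowest S phase levels, replicates 1 (4.96) and 3 (4.80), had the highest p53 target levels (6.26 and 6.27), and CDKN1A at 1069 and 1204 CPM against 593 and 561 CPM in replicates 2 and 4. What sets the replicate numbers apart was not tested.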
